A study of Homo sapiens with 22 samples.

How the data were processed

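The series holds 1 array per sample of total RNA from human primary prostate cancer, 3 untreated samples and 19 foci treated with neoadjuvant androgen deprivation. The deposited values are on the log2 scale and were made with RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays to a common distribution and summarises the probes of each feature. Its version, settings, annotation and genome build, and whether all arrays were processed together, are not given in the sources used here. Array quantiles were not identical, and the interquartile range over genes ran from 1.21 to 1.96 across arrays. The array medians over all features lay between 5.14 and 5.54, and the highest value on an array between 19.7 and 19.9. The values carry no read depth, and precision rests on the number of arrays and on how widely donors vary. RMA compresses differences near the background and near the ceiling, and 21 of the tested genes reached 19.9 on at least 1 array. The mean of 23 background probe sets lay between 3.43 and 3.71. No slide, scan date or other batch is given in the labels, so a batch could not be tested, and any batch that held the untreated samples alone cannot be told apart from treatment.

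Features were named through the platform annotation table. Of 70523 features, 23781 had 1 gene symbol, 1543 several and 45199 none. Of the features with 1 symbol, 21497 were matched by gene identifier to current symbols, and 0 symbols changed. Features with several symbols or none stayed out of the gene tests. 88 features of Y-linked genes and XIST were left out. For the 455 genes with more than 1 feature, the feature with the highest mean over donors was used, which left 22401 genes. No filter on dim genes was applied. No coordinates are printed, because the annotation build is not given.

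Samples were grouped by the treatment given in the labels. The labels tie foci to donors, so the donor was the replicate, and the log2 values of the 2 foci of a donor were averaged. Foci of one donor were more alike over all genes than foci of different donors, as the report gives. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes at 0.05. Standard errors and 95% intervals come from that model, which takes a common variance per gene for both groups. The intervals may be too narrow for genes that vary more among untreated donors.

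37 gene lists (androgen response, steroid and receptor biology, cell types of the prostate and of neighbouring tissue, and stress, metabolic and signalling pathways) were fixed before the data were examined, as were the tests, the alternative settings named first and the rule for naming genes. They held 901 genes, of which 805 were measured. A list score was the mean over its genes of the log2 value minus the array median over genes, averaged per donor. Median changes of list members come from the gene test, without subtraction of the array median. Over all genes the median change was 0.03. Scores were compared with a two-sided exact permutation test over all 560 splits of the 16 donors, adjusted over the lists. The smallest p this test can give is 0.00357. Camera with a preset correlation of 0.01, camera with an estimated correlation and fry were run as alternatives. The likeness of foci was measured with the consensus correlation of limma's duplicateCorrelation and, per list, with a one-sided permutation test (100000 resamples) of the mean difference between foci of one donor. Relations to the androgen-induced score were tested with Pearson's r and Spearman's rho and 100000 permutations, adjusted over 12 relations.

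Named genes are the 10 largest rises and the 10 largest falls among genes past the threshold for which at least 11 of 13 treated donors lay on the same side of the untreated mean, 14 genes fixed beforehand, of which 3 are not analysed here, and up to 4 members with the smallest adjusted p of each list described in detail. Genes that vary between people (immunoglobulin, T-cell receptor variable and HLA genes) were counted and not named, and 1 such gene passed.

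Alternatives covered the handling of foci, features of a gene, a filter on dim genes, scaling, the variance model, array weights and each untreated sample left out. After the data were examined, settings for the spread of array values, cyclic loess between arrays and protein-coding genes only were added. The median change of a list was then also set against those of 10000 random lists of genes of the same level. The random genes were drawn independently, so these shares do not allow for genes that vary together or for the number of donors. Another background correction, a slide or scan date block and a covariate from control probe sets of the 2 ends of messengers were named beforehand and not run, since the values used here do not hold what they need.

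The gene test was tested on simulated data for 22401 genes, 3 and 13 donors and 200 changed genes. It recovered 75% of genes changed by 1 and 95% of genes changed by 2 on the log2 scale, with 5.03% false calls and 0 calls with no change put in. A donor correlation of 0.4 put in was recovered as 0.417. The list test recovered 10 of 10 lists lowered by 1 on the log2 scale and called 0 of 19 lists with no changed gene, and the counts were the same with the lists lowered by 0.75 or 0.35, sizes added after the results were seen. The 10 lists were lowered together. With 37 lists, the smallest exact p passes the adjustment by itself only if 3 lists reach it. The simulation therefore does not show recovery where fewer than 3 lists shift. The simulated genes varied independently, unlike genes of a real list, so recovery in real data may be lower. Simulated genes also had the same spread in both groups, and simulated arrays did not differ in spread. False calls in real data may therefore be more frequent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the list tests and figures.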

Results

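Gene expression was measured on microarrays in total RNA from 22 samples of human primary prostate cancer. The comparison set 3 untreated tumours from 3 donors against 19 tumour foci that had been exposed to neoadjuvant androgen deprivation, a treatment given before surgery that lowers androgen signalling, from 13 donors. 6 of the treated donors gave 2 foci and 7 gave 1. The foci of a donor were averaged, so that the comparison ran over 3 untreated and 13 treated donors. 70523 array features were measured, of which 22401 genes with a single symbol were tested. Values are on the log2 scale, with array medians between 5.14 and 5.54, and the number of arrays, above all the 3 untreated ones, limited the precision. The middle range of gene values was narrower on the treated arrays, with an interquartile range of 1.54 ± 0.176 (SD, n = 13 donors) against 1.72 ± 0.077 (SD, n = 3).

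The first question was which genes differed between treated and untreated tumours. The largest fall was that of PCA3, a long noncoding RNA made mostly in prostate, from 14.14 ± 0.96 (SD, n = 3) to 7.72 ± 0.97 (SD, n = 13), 85.4-fold lower. ABCC4, an exporter of cyclic nucleotides and drugs, fell from 12.98 ± 0.34 to 6.63 ± 0.72, 81.7-fold lower. The cold-sensing channel TRPM8, the relaxin hormone gene RLN1 and the retinol dehydrogenase gene RDH11 fell by 5.37, 5.14 and 4.49 on the log2 scale. RLN1 ran from 4.01 to 14.05 among untreated and from 3.95 to 5.32 among treated donors. Its lowest untreated donor thus lay within the treated range. The condensin subunit gene NCAPD3 fell by 4.41 and the sodium bicarbonate cotransporter gene SLC4A4 by 4.30. The other 3 of the 10 largest falls were SNORA71D, SNORA22 and SNORA79, small nucleolar RNAs of the H/ACA class, which guide pseudouridylation of ribosomal RNA, and they fell by 4.41, 4.27 and 4.14. For each of these 10 genes, 13 of 13 treated donors lay below the untreated mean. The rule for naming genes asked for at least 11, and 749 of all 760 genes past the threshold had 13 of 13 on the same side.

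Rises were smaller. ANXA1, an annexin that glucocorticoids induce, rose from 6.33 ± 0.41 (SD, n = 3) to 8.05 ± 0.79 (SD, n = 13), 3.3-fold higher. The transcriptional repressor gene TRPS1 rose by 1.36, ZFP36L1, which promotes decay of AU-rich messengers, by 1.13, the centrosomal gene CEP126 by 0.95 and the secreted-protein gene OLFML1 by 0.88 on the log2 scale. The remaining 5 of the 10 largest rises were short RNA features, MIR548I3 (1.25), MIR548I1 (1.07), RNA5SP260 (1.17), RNA5SP97 (0.92) and RNA5SP248 (0.91). These belong to families of near-identical copies, so their identity is uncertain.

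In limma's moderated test with Benjamini-Hochberg adjustment, 760 of 22401 genes differed, 697 lower and 63 higher in treated tumours. With an added log2 change of at least 1, 292 were lower and 6 higher. The share of lower genes was 91.7%, and it was 75.1% (423 lower, 140 higher) when the interquartile range of each donor's arrays entered the model as a covariate, a setting chosen after seeing the data. Without the 5 treated donors whose arrays had an interquartile range under 1.5, also chosen after seeing the data, 319 genes were lower and 56 higher. There RLN1, RDH11, SNORA71D, MIR548I1, CEP126 and RNA5SP97 no longer passed with fewer donors, while their changes were -5.21, -4.49, -4.21, 0.89, 1.08 and 0.97. Of the list members named further on, ACLY (-1.82), NDUFS1 (-0.45), SMS (-3.55), BNIP3 (-1.61), GPI (-0.67), VEGFA (-1.54) and CD3E (0.50) did not pass in that setting either. Other scalings with all donors also ended calls of genes named here. With quantile normalization these were MIR548I3, MIR548I1, SNORA71D, SNORA79, KRT8, PRSS8, AMACR, CD3E, SC5D, NDUFA5, NDUFS1, GPI and VEGFA (limma adjusted p from 0.052 to 0.162), where KRT8, GPI and PRSS8 had changes of -0.56, -0.46 and -0.43. With array spread as a covariate they were MIR548I3 (0.92), MIR548I1 (0.86), RNA5SP248 (0.87), RDH11 (-4.32), SNORA71D (-4.13), AMACR (-2.58), CD3E (0.43), NDUFS1 (-0.41) and VEGFA (-1.50). With cyclic loess they were MIR548I3 (1.54), MIR548I1 (1.37), SNORA71D (-4.07), KRT8 (-0.70), PRSS8 (-0.50) and CD3E (0.71). Other handling of foci, features, centring, weights or variance ended the calls of ANXA1, ZFP36L1 and RNA5SP260 and of some of these genes. ZFP36L1 had a change of 0.57 (limma adjusted p = 0.0909) with the mean of its features.

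The count rested on the untreated samples. It was 245 without untreated replicate 1, 695 without replicate 2 and 318 without replicate 3, and 144 of the 760 genes, 142 lower and 2 higher, passed in each of these 3 fits as well as with all samples. Of the 10 largest falls, PCA3, ABCC4, TRPM8, NCAPD3 and SLC4A4 passed in each fit. RLN1, whose untreated SD was 5.08, fell by 2.85 without replicate 1 (limma adjusted p = 0.167). Its change was -7.87 (limma adjusted p = 2.53e-06) without replicate 2 and -4.70 (limma adjusted p = 0.125) without replicate 3. RDH11, SNORA71D, SNORA22 and SNORA79 lost their calls without replicate 1 or 3, where the changes were -3.83 and -3.73, -3.39 and -4.58, -3.51 and -4.14, and -3.48 and -3.73 in that order of genes. SNORA71D also lost its call without replicate 2 (-5.27, limma adjusted p = 0.0503). None of the 10 largest rises kept its call without each of the 3 in turn, and ANXA1 changed by 1.55, 1.95 and 1.67 without replicates 1, 2 and 3.

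**Figure D1:**
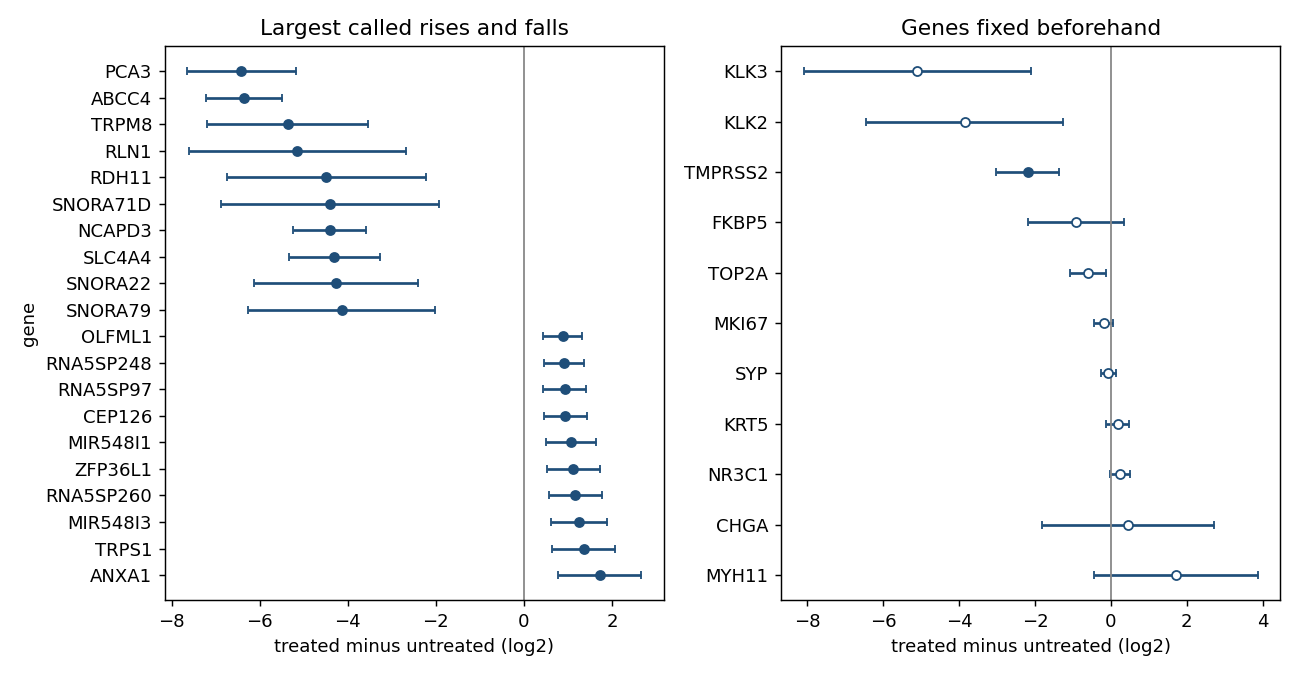
Treated minus untreated difference on the log2 scale for the 20 genes with the largest falls and rises past the threshold (left) and for 11 genes fixed beforehand (right). Points are limma estimates over 3 untreated and 13 treated donors, bars are 95% confidence intervals, filled points passed an adjusted p of 0.05 and open points did not. The bars rest on a common variance per gene for both groups and may be too short where untreated donors vary more. The falls on the left reach -6.42 for PCA3, while the largest rise is 1.72 for ANXA1.

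The second question was what happened to genes that the androgen receptor is known to induce in prostate. Of the 33 measured members of that list, 21 fell, none rose and 12 did not pass over all genes tested. Adjusted over the list alone, 27 fell. All 33 had a negative change, with a median of -2.06. Besides ABCC4, the members with the smallest adjusted p were RAB3B, a regulator of vesicle secretion (fell by 3.17), HERC3, a ubiquitin ligase (fell by 1.28), and PMEPA1, a membrane protein that dampens TGF-beta signalling (fell by 1.10). All 4 passed without each untreated sample in turn. The list score, the mean log2 value of its genes above the array median, was 4.12 ± 0.79 (SD, n = 3) in untreated and 1.89 ± 0.39 (SD, n = 13) in treated donors, a difference of -2.24, or 4.71-fold lower. The score lay below the untreated mean in 13 of 13 treated donors, with p = 0.00357 in a two-sided exact permutation test, the smallest p that 560 splits can give. The difference lay between -2.68 and -1.91 without each untreated sample in turn (exact p = 0.019, the smallest p of these smaller tests).

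Single members differed in how firmly they moved. KLK3, which encodes prostate-specific antigen, had 15.51 ± 1.27 (SD, n = 3) in untreated and 10.42 ± 2.49 (SD, n = 13) in treated donors, a difference of -5.09 that did not pass (limma adjusted p = 0.0605). KLK2, a related protease gene, had a difference of -3.85 (limma adjusted p = 0.104). Values of both spread widely among treated donors, and KLK3 passed in 5 alternative settings. The protease gene TMPRSS2 fell by 2.19 (limma adjusted p = 0.00567, 13 of 13 donors lower), and by 1.60 without untreated replicate 1 (limma adjusted p = 0.0592). FKBP5, a co-chaperone gene that androgens and glucocorticoids both induce, had a difference of -0.91 (limma adjusted p = 0.445, 12 of 13 lower).

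Of 37 gene lists, 7 shifted in the exact permutation test after Benjamini-Hochberg adjustment, all toward lower values in treated donors, and 0 shifted higher. With the median over members as the score the exact test called 5 lists lower and 1 higher, and with genes scaled to unit SD 7 lower and 1 higher, the WNT target list both times. At an unadjusted p under 0.05, 8 were lower and 1 higher. In each of the 7, 13 of 13 treated donors lay below the untreated mean. Adjusted p was 0.0378 for the polyamine list and 0.022 for the other 6. The androgen-induced list (adjusted p = 0.00709) and the sterol and lipid synthesis list (adjusted p = 0.0299) also passed camera with an estimated correlation between genes. Camera with a preset correlation of 0.01 called 8 lists lower and 8 higher, and fry called 7 lower and 2 higher, the basal epithelium and WNT target lists. The 7 lists kept their direction without each untreated sample in turn, and none of their differences moved by over 1.5 times. With these fewer samples 0 lists passed the adjustment, although the 7 had unadjusted exact p under 0.05 each time.

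Genes of protein folding in the endoplasmic reticulum fell as a group. The score of the unfolded protein response list went from 2.71 ± 0.176 (SD, n = 3) to 1.79 ± 0.284 (SD, n = 13), and camera gave adjusted p = 0.0932 with an estimated correlation. 11 of its 24 measured genes fell, 13 did not pass and none rose, and 16 fell adjusted over the list alone. The chaperone gene HSPA5 fell by 2.56, the disulfide isomerase genes PDIA3 and PDIA4 by 2.31 and 1.08, and the chaperone gene HYOU1 by 1.01. All 4 passed without each untreated sample in turn. Markers of luminal epithelium, given below, fell by 0.75 in the same donors. Whether this list fell apart from those markers was not tested, nor was it for the sterol, polyamine and oxidative phosphorylation lists that follow.

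The sterol and lipid synthesis list fell by 0.49, with 10 of 29 genes lower, none higher and 14 lower adjusted over the list alone. ACACA, which makes malonyl-CoA for fatty acid synthesis, fell by 2.41. ACLY, which supplies cytosolic acetyl-CoA, fell by 2.05, the fatty acid elongase gene ELOVL7 by 1.14 and the sterol desaturase gene SC5D by 0.94. ACLY lost its call without untreated replicates 1 and 3, where its changes were -1.64 and -1.84. With the median over members as the score, the list difference was -0.21 (exact test, adjusted p = 0.103).

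The polyamine list fell by 0.75 with 1 of 12 genes past the threshold, or 2 adjusted over the list alone. Its median member changed by -0.28, and 6.02% of 10000 random lists of genes of the same level had a median as low, so few members carry the difference, and camera gave adjusted p = 0.0963 with an estimated correlation. The gene that fell was SMS, spermine synthase (-4.01, and -2.45 with limma adjusted p = 0.0916 without untreated replicate 1). It is also a member of the androgen-induced list, and 2 genes are shared between the 2 lists. AZIN1, AMD1 and SRM had changes of -0.91, -1.72 and -0.27 that did not pass. The oxidative phosphorylation list fell by 0.35, with 3 of 41 genes lower and 11 adjusted over the list alone, and camera gave adjusted p = 0.274 with an estimated correlation. The 3 were the complex I subunit genes NDUFV2 (-1.30), NDUFS1 (-0.60) and NDUFA5 (-0.43), and NDUFB10 had -0.58 without passing. NDUFV2 passed without each untreated sample in turn. NDUFA5 did not pass without replicate 1 (-0.40) or replicate 3 (-0.40), nor NDUFS1 without these 2 (-0.67 and -0.41). With the first focus of each donor in place of the mean, the list difference was -0.35 with exact adjusted p = 0.0991. The median member of the oxidative phosphorylation list changed by -0.25. Random lists of genes of the same level had a median of -0.10, and 2.01% of them were as low, so part of the fall goes with level.

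Markers of luminal epithelium, the secretory cell layer of the prostate, fell by 0.75 as a list, from 1.77 ± 0.285 (SD, n = 3) to 1.02 ± 0.269 (SD, n = 13), and camera gave adjusted p = 0.0963 with an estimated correlation. 9 of 21 genes fell, 12 did not pass, and 15 fell adjusted over the list alone. The peptidase gene DPP4 fell by 3.69, the keratin genes KRT18 and KRT8 by 1.17 and 0.97 and the protease gene PRSS8 by 0.64. KRT8 and PRSS8 lost their calls without untreated replicate 1 (-0.89 and -0.55) or 3 (-0.76 and -0.61). Markers of prostate tumours fell by 1.16 as a list, with 3 of 23 genes lower and 11 adjusted over the list alone, and camera gave adjusted p = 0.0963 with an estimated correlation. These 3 were PCA3, the Golgi membrane protein gene GOLM1 (-3.50) and the racemase gene AMACR (-2.65, 12 of 13 donors lower). AMACR lost its call without untreated replicate 1 (-2.44) or 2 (-2.08). ENTPD5, which acts in glycoprotein folding, had -1.68 and did not pass. With the median over members as the score, the tumour marker difference was -0.39 (exact test, adjusted p = 0.198). The labels give neither the tumour cell content of a sample nor how it was dissected. Falls of these and the other lists were therefore not separated from a difference in cell composition.

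**Figure D2:**
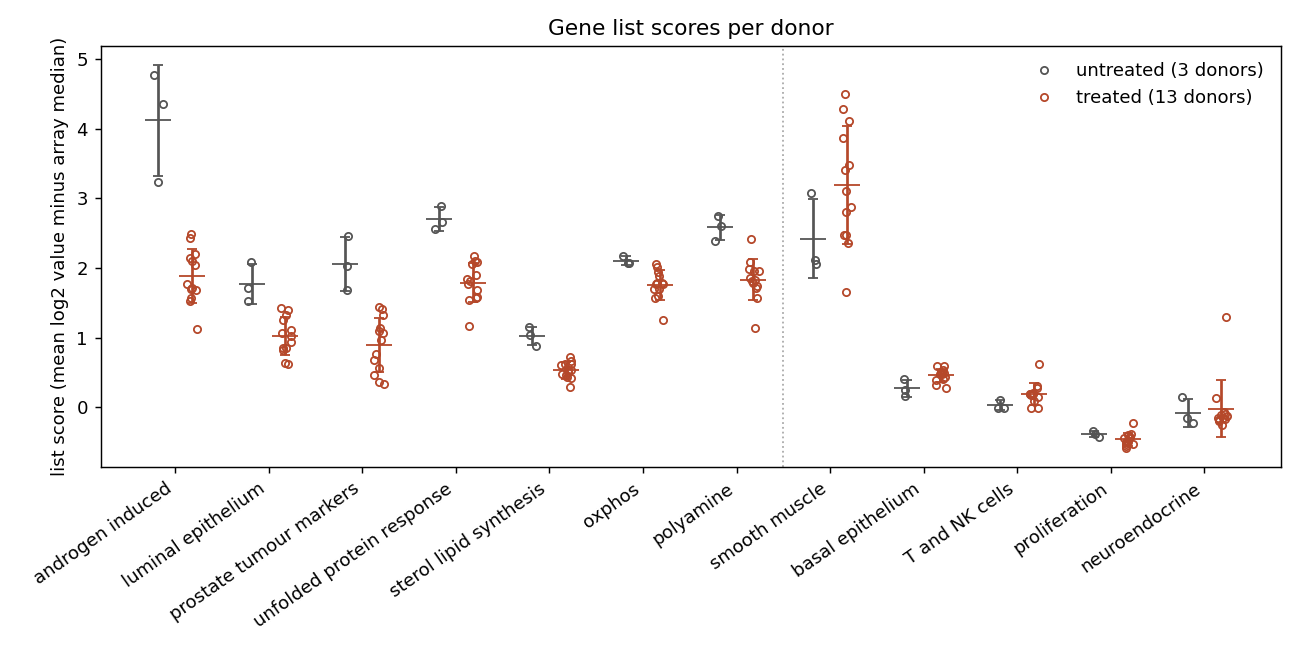
Scores of 12 gene lists in 3 untreated (grey) and 13 treated (red) donors. The vertical axis is the mean log2 value of a list's genes minus the array median; open circles are donors, horizontal bars are means and whiskers are SDs. The 7 lists left of the dotted line passed the exact test, and the androgen-induced score differs by -2.24 while the smooth muscle score differs by 0.77 without passing.

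The other 30 lists did not pass. Without 1 or another of the untreated samples, 7 of the 30 turned sign and 12 more moved by over 1.5 times, so the small differences that follow depend on single untreated samples. Among lists of other cell types, smooth muscle had the largest difference, 0.77 (exact p = 0.168, adjusted p = 0.388, 11 of 13 donors higher). Its score varied widely, with 2.42 ± 0.57 (SD, n = 3) against 3.19 ± 0.85 (SD, n = 13), and the difference was 1.16 without the donors with narrow arrays. MYH11, the smooth muscle myosin heavy chain, had a change of 1.71 (limma adjusted p = 0.403), DES 1.61, LMOD1 1.15, TAGLN 0.99 and SMTN 0.26, and 0 of 20 members passed, although all 20 changes were positive. Basal epithelium had 0.19 (adjusted p = 0.0881), with 1 of 18 genes past the threshold. That gene was ITGA6, an integrin, which fell by 0.74. It lost its call without each untreated sample in turn, with changes from -0.79 to -0.66. KRT14, KRT5, DST and ITGB4 had changes of 0.37, 0.17, 1.29 and 0.15 that did not pass. T and NK cells had 0.17 (adjusted p = 0.192), and 1 of 27 members passed. It was CD3E, a T-cell receptor complex gene, which rose by 0.61 and lost its call without each untreated sample in turn, with changes from 0.53 to 0.74. CD4, CD6 and CD2 had 0.24, 0.27 and 0.47 without passing.

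Differences for the remaining cell type lists were 0.11 for fibroblasts and matrix, -0.02 for endothelium, 0.14 for club and hillock cells, 0.06 for neuroendocrine cells, 0.02 for nerve and Schwann cells, 0.11 for seminal vesicle and urothelium, 0.05 for adipocytes, 0.07 for skeletal muscle, -0.07 for B and plasma cells, 0.14 for myeloid cells, 0.02 for mast cells and 0.13 for blood cells. Without each untreated sample in turn, fibroblasts and matrix ranged from -0.01 to 0.31, endothelium from -0.09 to 0.05, club and hillock cells from 0.01 to 0.34, neuroendocrine cells from -0.01 to 0.18 and nerve and Schwann cells from -0.03 to 0.04. For endothelium and for B and plasma cells, the median change of the members had the opposite sign (0.05 and 0.06). These medians were taken without subtracting the array median, and the median change of all genes was 0.03, so these signs are weak evidence. Smooth muscle, T and NK cell, basal, skeletal muscle and myeloid lists were called higher by camera with a preset correlation of 0.01, and none of them with an estimated correlation (adjusted p from 0.358 to 0.659).

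Neuroendocrine markers showed no detectable shift as a group, and although the mean difference was positive, 3 of 13 treated donors lay above the untreated mean. The highest treated score was 1.29, against 0.14 for the next treated donor and 0.15 for the highest untreated donor. The positive mean difference thus rests largely on the donor with the highest score. CHGA, which encodes chromogranin A, had 5.86 ± 0.73 (SD, n = 3) and 6.30 ± 1.91 (SD, n = 13), limma adjusted p = 0.842, with 4 of 13 treated donors higher. Its highest value was 12.02 among treated and 6.70 among untreated donors. Whether that treated donor also had the highest list score was not examined. SYP, synaptophysin, had a difference of -0.08, NCAM1 0.38, CPE -1.44, ENO2 0.25 and SCG5 0.42, and 0 of 27 members passed. The proliferation list had a difference of -0.08 (adjusted p = 0.396), with 0 of 45 members past the threshold. MKI67 had -0.18, TOP2A -0.60, CCNB2 -0.33, NCAPG -0.26 and the replication helicase gene MCM6 0.33. The proliferation scores were low on these arrays in both groups, -0.38 ± 0.042 (SD, n = 3) and -0.46 ± 0.091 (SD, n = 13) relative to the array median. The median change of the members, -0.023, lay at or above that of 0.02% of 10000 random lists of genes of the same level, whose median was 0.076.

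The steroidogenesis list had a difference of -0.01 with a median change of 0.14, of opposite sign. 1 of its 25 genes passed, HSD17B4, a peroxisomal dehydrogenase gene, which fell by 1.61 and passed without each untreated sample in turn. CYB5A, CYP21A2 and AKR1C1 had -0.98, 0.20 and 0.44 without passing, and CYP21A2 and AKR1C1 have close copies in the genome. NR3C1, the glucocorticoid receptor gene, had a difference of 0.23 (limma adjusted p = 0.359) and the glucocorticoid-induced list 0.05 (adjusted p = 0.903). Genes repressed by androgen had 0.05, and -0.05 without untreated replicate 1. The median change of their 13 members was 0.24, with 10 members above 0, at or above that of 99.9% of 10000 random lists of genes of the same level. That share was 100% for the smooth muscle, fibroblast and matrix, and immediate early lists, so it was not particular to androgen-repressed genes. The exact test over donors gave p = 0.571 for the androgen-repressed list. Interferon response had -0.08, and 0.13 without replicate 2. Steroidogenesis also turned sign without replicate 3 (0.0068). The glucocorticoid-induced list had 0.24 without the donors with narrow arrays. For nuclear receptors and cofactors the difference was -0.10, with a median of 0.10. Without the donors with narrow arrays 3 lists turned sign, nuclear receptors and cofactors (0.0033), endothelium (0.03) and heat shock (0.08).

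The hypoxia and glycolysis list had -0.25 (exact p = 0.0179, adjusted p = 0.0826). 3 of its 25 genes passed and fell, the mitophagy gene BNIP3 (-1.89), the growth factor gene VEGFA (-1.56) and the glycolytic gene GPI (-0.76), and TPI1 had -0.44 without passing. VEGFA did not pass without untreated replicate 1 (-1.39) or 3 (-0.98), BNIP3 without replicate 3 (-1.65), and GPI without each in turn (-0.84 to -0.69). Immediate early genes had 0.53 (adjusted p = 0.396), 0.29 without untreated replicate 1, 0.79 without replicate 3 and 0.81 without the donors with narrow arrays, with IER3 at 0.42, KLF6 at 0.59, ATF3 at 0.55 and PPP1R15A at 0.39, none of which passed. The remaining differences were -0.15 for DNA repair, -0.09 for p53 targets, -0.13 for heat shock, -0.24 for ribosomal proteins, 0.14 for TGF-beta and mesenchymal genes and -0.07 for receptor tyrosine kinases. The median ribosomal protein gene changed by -0.18, against -0.21 for random lists of genes of the same level. WNT targets had 0.16 (exact p = 0.0571, adjusted p = 0.192), with 13 of 13 treated donors higher and 0 of 19 members past the threshold, or 1 higher adjusted over the list alone. Fry called this list higher (adjusted p = 0.00336), as did camera with a preset correlation (adjusted p = 0.0118), while camera gave adjusted p = 0.0963 with an estimated correlation. The median change, taken without subtracting the array median, had the opposite sign for p53 targets (0.06) and receptor tyrosine kinases (0.09). For heat shock it was 0.01, below the median change of all genes (0.03), so its sign does not conflict with that of the score.

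The third question was how alike foci of one donor were. Over all genes the consensus correlation between foci of one treated donor was 0.365 ± 0.104 (jackknife SE over 6 donors with 2 foci). Leaving out each of these donors in turn gave 0.304 to 0.440. Array values correlated across genes, which are not independent replicates, with a median r of 0.965 between foci of one donor and 0.941 between foci of different donors.

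Scores of the lists were then compared between the 2 foci of a donor and between foci paired at random. Smooth muscle scores differed by 0.367 on average within a donor and by 0.961 in random pairs (one-sided permutation p = 0.0047, adjusted p = 0.0731). Heat shock scores differed by 0.169 and 0.506 (permutation p = 0.00193, adjusted p = 0.0714). The androgen-induced score differed by 0.560 within a donor and by 0.529 in random pairs (permutation p = 0.593), so no likeness of foci was detectable for it. In the permutation test 0 of 37 lists passed after adjustment and 7 had an unadjusted p under 0.05.

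**Figure D3:**
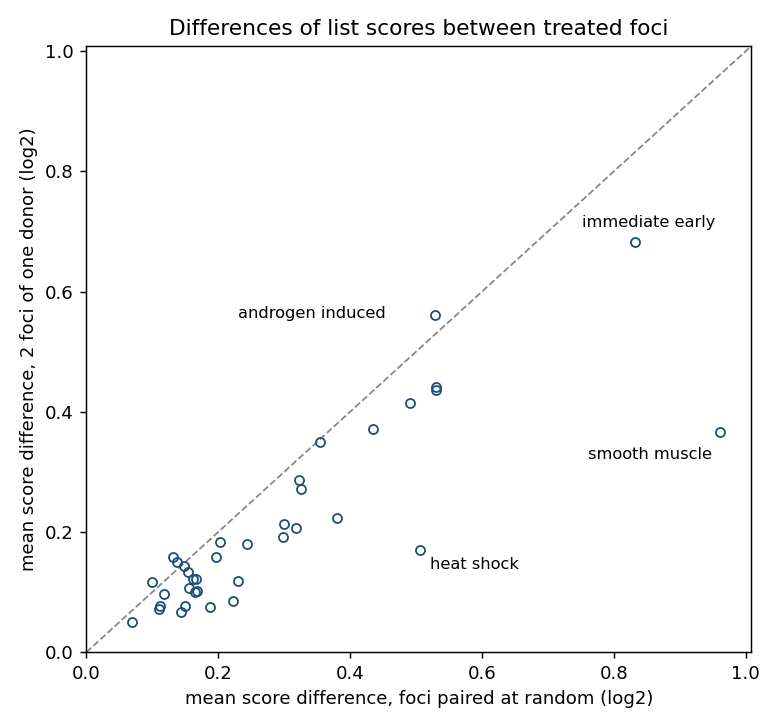
Mean absolute difference of each of 37 list scores (log2) between 2 foci of one treated donor (vertical axis, 6 donors) and between foci paired at random (horizontal axis, 19 foci). Each circle is a list and the dashed line marks equal differences; smooth muscle lies at 0.367 against 0.961, and the androgen-induced list at 0.560 against 0.529.

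The last comparison asked which measures followed the androgen-induced score among the 13 treated donors. Of 12 relations, 0 passed after Benjamini-Hochberg adjustment for Pearson's r or Spearman's rho. At an unadjusted permutation p under 0.05 there were 0 for r and 2 for rho, NR3C1 and the luminal list. NR3C1 had r = 0.52 (permutation p = 0.0653, adjusted p = 0.358) and rho = 0.58 (permutation p = 0.0422, adjusted p = 0.297), and r = 0.41 without the 2 donors farthest from the median score. The luminal score had r = 0.50 (permutation p = 0.0848, adjusted p = 0.358) and rho = 0.56 (permutation p = 0.0495, adjusted p = 0.297), and r = 0.19 without these 2 donors, so that relation rests in part on them, although their removal also narrows the range of the score. Among the 8 donors with wider arrays r was 0.57. The other 10 relations had r between -0.45 for T and NK cells and 0.49 for immediate early genes. The androgen-induced score itself had r = 0.43 (permutation p = 0.140) and rho = 0.41 with the interquartile range of the arrays.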

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

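Features without a gene symbol were outside the gene comparison, and some carried a signal above the untreated samples. Of 42001 such features tested in the same limma model, 8 were higher and 146 lower in treated tumours. Their identity was not analysed here.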

How the results depend on the processing

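Settings for array spread, cyclic loess and protein-coding genes were chosen only after the results were seen. The count of 760 changed genes lay between 529 with quantile normalization and 1086 with array weights in the other settings of foci, features, dim genes, scaling, variance, array spread as a covariate, cyclic loess and gene class. It left that range with a log2 change of at least 1 (298, fewer by construction), without the treated donors with narrow arrays (375, fewer donors) and without untreated replicate 1 or 3 (fewer samples; 245 to 695 over the 3 left out in turn, the highest without replicate 2). The 563 genes called with array spread as a covariate shared 430 with the 760, and the 529 after quantile normalization shared 460. The androgen-induced list kept its direction in each setting run, with p under 0.05 before any adjustment over lists, with differences from -2.68 to -1.91 (log2), or -1.83 in SD units when genes were scaled. The count of 7 shifted lists lay between 6 and 9 with other foci, features, scores and fry. It was 16 with a preset correlation in camera and 2 with an estimated one. The gap between these 2 comes from the correlation between genes that camera assumes, and the cause of the rest was not tested. It was 0 without each untreated replicate in turn and 0 without the donors with narrow arrays, with fewer splits. There the smallest exact p, 0.019 or 0.0121, passes only if 15 or 9 lists reach it, and 6 to 9 or 6 did. The 7 lists stayed lower with unadjusted exact p under 0.05 in each of these 4 settings. List likeness within donors went from 0 to 4 of 31 lists with members in the upper 50% by mean, and the cause was not tested. The correlation between foci lay between 0.304 and 0.440, and 0 relations passed in each of the 5 other settings. Among 1470 values of named genes under other settings, 1 changed direction, SYP (-0.18 to 0.085 without each untreated replicate), which did not pass. Of the 48 named genes past the threshold, 20 stayed past it without each untreated replicate in turn. Quantile normalization ended 13 of these 48 calls, array spread as a covariate 9 and cyclic loess 6, and 33 of the 48 stayed past the threshold in all 3. In all settings that keep all donors 30 stayed past it. These genes kept their direction. No paired analysis was possible because treated and untreated samples come from different donors. Another background correction, a batch block and an RNA quality covariate were not run.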

Other observations

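The gene lists of the first 2 paragraphs here, and all tests in this part except the count over other splits of the donors, were chosen only after the main results were seen. Genes of the secretory pathway were lower in treated tumours beyond the chaperones of the report. Glycosylation genes fell by 0.68 as a list (adjusted p = 0.00663 in an exact permutation test over 13 added lists, 13 of 13 donors lower), and 11 of 32 genes passed in limma. Among them were the mucin-type transferase gene GALNT7 (-2.88) and the oligosaccharyltransferase subunit genes RPN2 (-1.62), STT3A (-1.58) and RPN1 (-1.08). Genes of transport between endoplasmic reticulum and Golgi fell by 0.66 (6 of 38 genes, 13 of 13 donors lower), with SEC23B (-1.37) and COPG1 (-1.50) among them. Proteasome subunit genes fell by 0.61 (4 of 28 genes), with PSMA6 at -1.63. Luminal markers fell by 0.75 in the same donors. The shifts of these 3 lists minus the luminal shift were 0.07, 0.09 and 0.15 (exact p = 0.693, 0.593 and 0.479), so these falls were not separated from that of the luminal markers. Metallothionein genes, which bind zinc and copper, fell by 1.29 (3 of 10 genes), from 2.88 ± 0.263 (SD, n = 3) to 1.59 ± 0.417 (SD, n = 13). MT1G, MT1F and MT1H, the 3 that passed, had -3.20, -2.73 and -2.55, though members of this family are close in sequence and single genes are uncertain. The list was written after gene results had been seen, and without these 3 the other 7 genes had a difference of -0.61 (exact p = 0.0393, 12 of 13 donors lower). The list's shift minus the luminal shift was -0.54 (exact p = 0.143), and 0.14 (exact p = 0.757) without these 3.

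Mitochondrial lists moved by less. The tricarboxylic acid cycle list fell by 0.39 (1 of 19 genes, IDH1, a cytosolic and peroxisomal enzyme, at -1.78), beta-oxidation and peroxisome genes fell by 0.33 (4 of 26 genes) and mitochondrial translation genes fell by 0.33 (2 of 36 genes). Zinc transporter genes fell by 0.43 as a list, with SLC39A6 at -2.83, while the median member changed by -0.05, so a few members carry the difference. Aminoacyl-tRNA synthetase genes fell by 0.36 with 0 of 19 genes past the threshold, and without the donors with narrow arrays they had -0.23 (exact p = 0.097). Ribosome biogenesis genes fell by 0.33 with 1 of 28 genes past it, PAK1IP1 (-3.29), whose fall had been seen before the list was written. Their median member changed by -0.12, and 6.33% of random lists of the same level had a median as low, so few members carry that difference. Features like 5S ribosomal RNA had a difference of 0.20 (exact p = 0.118, 486 features).

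The count of 760 changed genes was set against other groupings of the donors. From the 560 possible splits of the 16 donors into 3 and 13, 100 were drawn. Of these 100, 2 gave as many genes, the real one included, a share under 0.05. The highest other split called 4735 genes, several times the real count, which points to a structure of the samples. Its group of 3 held 0 untreated donors and 3 treated donors with narrow arrays, and no other split with 3 such donors was drawn. A group of 3 donors with narrow arrays thus gave more calls than the real grouping, in the 1 such split drawn. Whether array spread itself or another trait of these donors gave those calls was not tested. The count therefore cannot exclude an accidental grouping along array spread. The next highest of the other splits called 66.

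Falls far outnumbered rises among the changed genes. Narrow arrays of 5 treated donors are a candidate explanation, since compressed values lower bright genes. Without these donors 85.1% of the called genes were still lower, against 91.7% in the main comparison. After cyclic loess, which removes a level-dependent difference between arrays, 82.9% were lower. Loess gave 689 genes lower and 142 higher, against 697 and 63, so that share moved mostly through more rises. These values argue against either as the whole cause, while a part may come from array spread, as the 75.1% with array spread as a covariate shows. A difference in preparation between untreated and treated samples stays open, since the labels give no batch, and loss of androgen-driven expression stays open as the biological explanation.

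Androgen-induced genes were lower by 2.24 in treated tumours. A lower share of luminal epithelium in the treated foci is a candidate explanation, since luminal cells respond most directly to androgen. The androgen-induced list fell by 1.49 more than the luminal list (difference of shifts -1.49, exact permutation p = 0.00357, the smallest possible, 13 of 13 donors). The lists differ in level, with untreated scores of 4.12 and 1.77. Since RMA compresses differences near the background, dimmer markers may fall less with a lower luminal share. The unequal falls therefore cannot decide on this explanation, and how much of the fall comes from cell composition stays open. Smooth muscle markers differed from endothelial markers by 0.79 (exact p = 0.107) and from fibroblast markers by 0.65 (exact p = 0.025), so other cell types did not clearly move alike.

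H/ACA small nucleolar RNAs fell as a class of 64 features, from 4.20 ± 0.985 (SD, n = 3) to 2.93 ± 0.415 (SD, n = 13; exact p = 0.0179, 13 of 13 donors lower), with 9 features past the threshold. The class was chosen because 3 members were among the 10 largest falls, and without these 3 the difference was -1.11 (exact p = 0.0214). Loss of short RNA in the treated preparations is a candidate explanation, but the C/D class, also short, had a difference of -0.13 (exact p = 0.471, 173 features, 8 past the threshold and lower) with a median change of 0.13, of opposite sign, and the 2 classes moved apart by -1.13 (exact p = 0.0143), or by -0.98 (exact p = 0.0214) without these 3. The C/D class was dimmer, with an untreated score of 1.61, so its values may be more compressed. Lists of 64 genes of the same level had a median change of -0.095, against -0.96 for the class (-0.90 without these 3). That match used 20 groups by level with an open top group, so the brightest features were set against dimmer genes. The 2 classes moved apart, but these comparisons cannot decide on loss of short RNA or a level-dependent difference between arrays. The wide spread of the untreated samples and an unrecorded difference in preparation keep the pattern open, and a link of the class to androgen deprivation is a hypothesis only.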
